A study of Homo sapiens with 9 samples.

How the data were processed

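The data are 9 RNA-seq libraries of total RNA from SH-SY5Y human neuroblastoma cells, 3 each after 72 h with vehicle, 10 µM or 20 µM citrinin. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which can be partly technical.

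Per the submitters' processing notes, reads were checked with FastQC, trimmed with cutadapt and aligned with STAR to GRCh38, and edgeR was used; versions and the annotation release are not given in the sources used here. The authors deposited, per library, STAR's table of raw counts per gene, with a count of both strands together and a count for each strand. Reads on either strand were about equally frequent (ratio 1.007 to 1.020 between strands), so the kit does not mark strand, the joint count was used, and a gene's reads cannot be told from those of an overlapping antisense gene. Reads set apart in those tables as unmapped (2.86% to 3.62%), mapped to several places (2.22% to 2.61%), outside genes (6.75% to 7.98%) or ambiguous between genes (9.51% to 10.1%) were left out of library sizes and tests, and 76.4% to 78.0% were assigned to genes. Reads that match more than 1 place were not counted, so values of near-identical paralogs and of genes with processed pseudogenes are uncertain. The authors also deposited a normalized table of 36838 genes in which the values are log2 CPM rather than CPM. Recomputing log2 CPM from the joint counts with TMM factors in edgeR gave 100% of its values within 1e-06. Tests on log2(CPM + pseudocount), chosen beforehand, therefore used this table turned back to CPM, by raising 2 to each value and subtracting the value of the table's minimum, with pseudocounts of 1 and 0.1.

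Library totals ran from 15678443 to 19604367 gene reads, and 3 reads in a library equal 0.153 to 0.191 CPM. Of 36838 genes with a read in any library, 17806 passed edgeR's filterByExpr at its default settings. TMM factors lay between 0.989 and 1.013. Gene symbols were matched for 61369 of 61487 identifiers. Coordinates, lengths and gene types are from GENCODE 29 on GRCh38, which holds 58312 of the identifiers. CPM values in the report are scaled with TMM.

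The planned test was edgeR's quasi-likelihood test with robust estimation on all 9 libraries, with 3 groups and no covariate, and Benjamini-Hochberg adjusted p below 0.05 (R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0). A fit with the replicate number as a block was planned as its alternative. Whether the numbers pair the samples was decided from the correlation of same-numbered libraries' deviations from their group means. All 9 same-numbered pairs had r of 0.457 to 0.685, above the limit of 0.1, while pairs with different numbers had r of -0.545 to 0.139, and 9 of 9 libraries correlated best with their own number. The replicate numbers come from the sample titles. They were therefore taken to pair the samples, and blocked results stand beside those of the planned fit. The planned fit left 6 residual degrees of freedom and the block 4. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom at least 8.85).

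The comparisons, the tests, the alternatives, 36 gene lists, a set of single genes to be reported whatever their p, and the rule for naming genes were fixed before the data were examined. The rule takes per comparison the 8 rising and 8 falling protein-coding genes (5 and 5 between the doses) with the largest change among those past the threshold, averaging at least 2 CPM and without overlap between the groups. It adds up to 4 members with the smallest p of each called list that moved in its direction, and where no gene passes, the 3 with the smallest p. Applying the rule to the blocked fit as well was decided after the data were seen. Of 962 symbols in the lists, 961 were matched. TH, one of the single genes, had 3 reads in the 9 libraries and was not tested.

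Gene lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 36 lists, and again with a correlation estimated per list. Limma's fry, which asks whether a list's genes move one way on balance without comparing them with other genes, was an alternative. With an estimated correlation the NRF2 list was the one list called, in all 3 comparisons without the block and at 20 µM against vehicle with it.

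The dose comparisons share their vehicle libraries, so 20 data sets of unchanged groups were simulated against the same controls. The scripts were tested on simulated counts for 20 µM against vehicle, with 17806 genes and the replicate effects and spread of the real libraries. For the recovery below 200 genes were changed. The genes of a further list were raised 1.25-fold, and calls among them were not counted as false. Without the block edgeR recovered 0% of genes changed 1.25-fold, 20% at 1.5-fold, 64% at 2-fold and 78% at 3-fold. With the block it recovered 54%, 90%, 94% and 100%, with 8 false among 194 calls. The counts were drawn from the blocked model, so the gain from the block is built in. They cannot show that the block suits the real libraries. The 200 changed genes were drawn from those averaging at least 2 CPM, so recovery below that level is not known. Alternatives were RLE size factors, library totals, no mitochondrially encoded genes, no filter, a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, fits of the 6 libraries compared, the counts of 1 strand, the authors' table, each library left out, a 2-fold limit and a threshold of 0.01.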

Results

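Transcript levels were measured by RNA-seq in SH-SY5Y cells, a human neuroblastoma line with features of immature sympathetic neurons. The cells were exposed for 72 h to vehicle, 10 µM or 20 µM citrinin, a mycotoxin made by Penicillium, Aspergillus and Monascus moulds. The series asked which transcripts change in these neuron-like cells after citrinin. Each of the 3 groups held 3 libraries, 9 in all. Reads assigned to genes came to 17157756, 17566221 and 17164852 in vehicle replicates 1, 2 and 3. They came to 17273034, 15678443 and 19604367 at 10 µM, and to 16700919, 17260562 and 17443340 at 20 µM. Mitochondrially encoded genes took 10.3% to 12.4% of the gene reads in a library.

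Libraries with the same replicate number resembled each other more than libraries of the same dose did. Replicate numbers accounted for 62.2% of the variance of log2 CPM (counts scaled to library depth) and doses for 13.6%. Both shares include noise between libraries, which was not subtracted, so 13.6% is not the size of a dose effect. The typical coefficient of variation between libraries of 1 group was 0.195 in the planned fit without a replicate term and 0.055 once the replicate number entered as a block. For that reason each comparison below gives both fits. "Rose" and "fell" are used of genes with an adjusted p below 0.05 in the fit with the replicate block, and no gene passed in the planned edgeR fit without it (115 at 10 µM, 387 at 20 µM and 210 between the doses had an unadjusted p below 0.05; DESeq2 without the block called 0, 11 and 0, and limma-voom 0 in each).

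**Figure D1:**
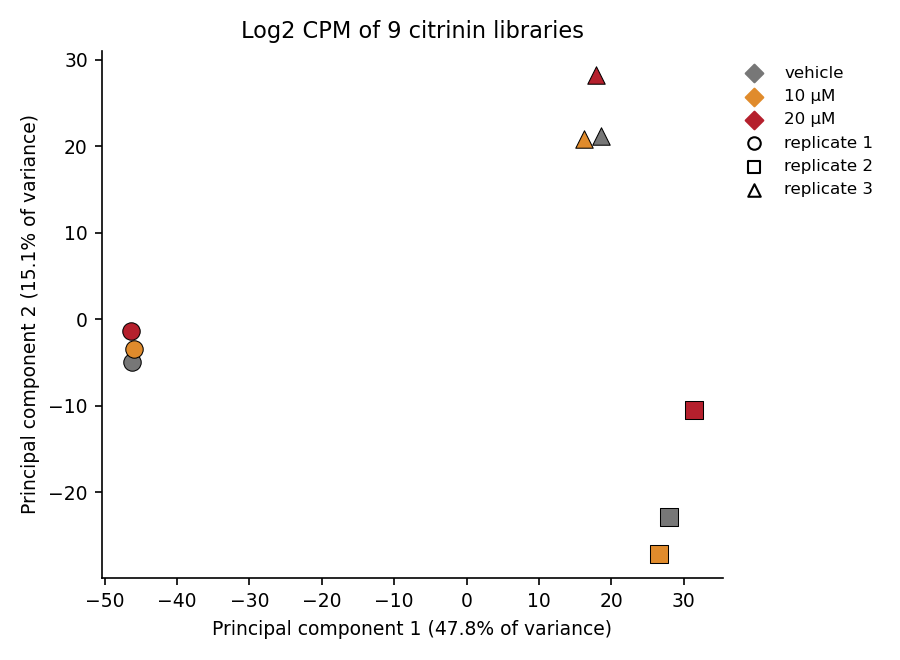
Principal components 1 (47.8% of variance) and 2 (15.1%) of log2 CPM in the 9 libraries, with dose as colour and replicate number as symbol. The 3 libraries of replicate 1 lie near -46 on component 1, and those of replicates 2 and 3 lie between 16.2 and 31.5.

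The first comparison set 20 µM citrinin against vehicle. Antioxidant genes driven by the transcription factor NRF2 were higher at 20 µM. NQO1, a quinone reductase, rose 1.97-fold, from 91.0 ± 5.13 to 179.6 ± 18.9 CPM (SD, n = 3 per group; log2 fold change 0.98 ± 0.06 SE). GCLM, a subunit of the enzyme that limits glutathione synthesis, rose from 46.3 ± 8.62 to 88.8 ± 19.4 CPM (0.93 ± 0.07). SLC7A11, the cystine importer, rose from 7.94 ± 0.53 to 24.2 ± 8.93 CPM (1.58 ± 0.15). OSGIN1, an oxidative stress-induced growth inhibitor, rose from 8.44 ± 1.41 to 20.5 ± 3.54 CPM (1.28 ± 0.11), and HMOX1, the inducible heme oxygenase, from 6.13 ± 0.79 to 12.5 ± 3.35 CPM (1.03 ± 0.16). In the edgeR fit with the replicate block the adjusted p was 1.22e-11 for NQO1, 5.69e-10 for GCLM, 2.20e-06 for SLC7A11, 2.34e-08 for OSGIN1 and 0.000344 for HMOX1. These 5 genes were higher in 3 of 3 same-numbered pairs of libraries, the pairs on which that fit is blocked, so this adds no independent support.

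Of the 27 NRF2 antioxidant genes tested, 20 rose, none fell and 7 did not pass; 24 rose when adjusted over the list alone. The list's median log2 fold change was 0.55, and camera with the replicate block gave an adjusted p of 2.22e-107, against 0.00963 with an estimated correlation. Without the block, camera's adjusted p was 1.61e-82, and 0.000813 with an estimated correlation. Fry called the list in both fits (adjusted p = 0.00417 with the block and 0.00226 without it). Thioredoxin reductase TXNRD1 (0.70 ± 0.05) and the drug exporter ABCC3 (0.53 ± 0.05) were among the risers. AKR1C3 (0.90 ± 0.08) and AKR1C1 (0.91 ± 0.14) also rose. These reductase genes and AKR1C2 are related in sequence. Reads that match more than 1 of them were not counted, so their levels may be incomplete. The organic anion transporter SLCO2B1, outside the list, rose by 1.04 ± 0.11. On GRCh38 with GENCODE 29 annotation, NQO1 (ENSG00000181019) spans 69706996 to 69726951 on chromosome 16, GCLM (ENSG00000023909) 93885205 to 93909456 on chromosome 1, and SLC7A11 (ENSG00000151012) 138164097 to 138242349 on chromosome 4. OSGIN1 (ENSG00000140961) spans 83948282 to 83966332 on chromosome 16 and HMOX1 (ENSG00000100292) 35380361 to 35394214 on chromosome 22. Counts were summed over the exons of each gene.

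**Figure D2:**
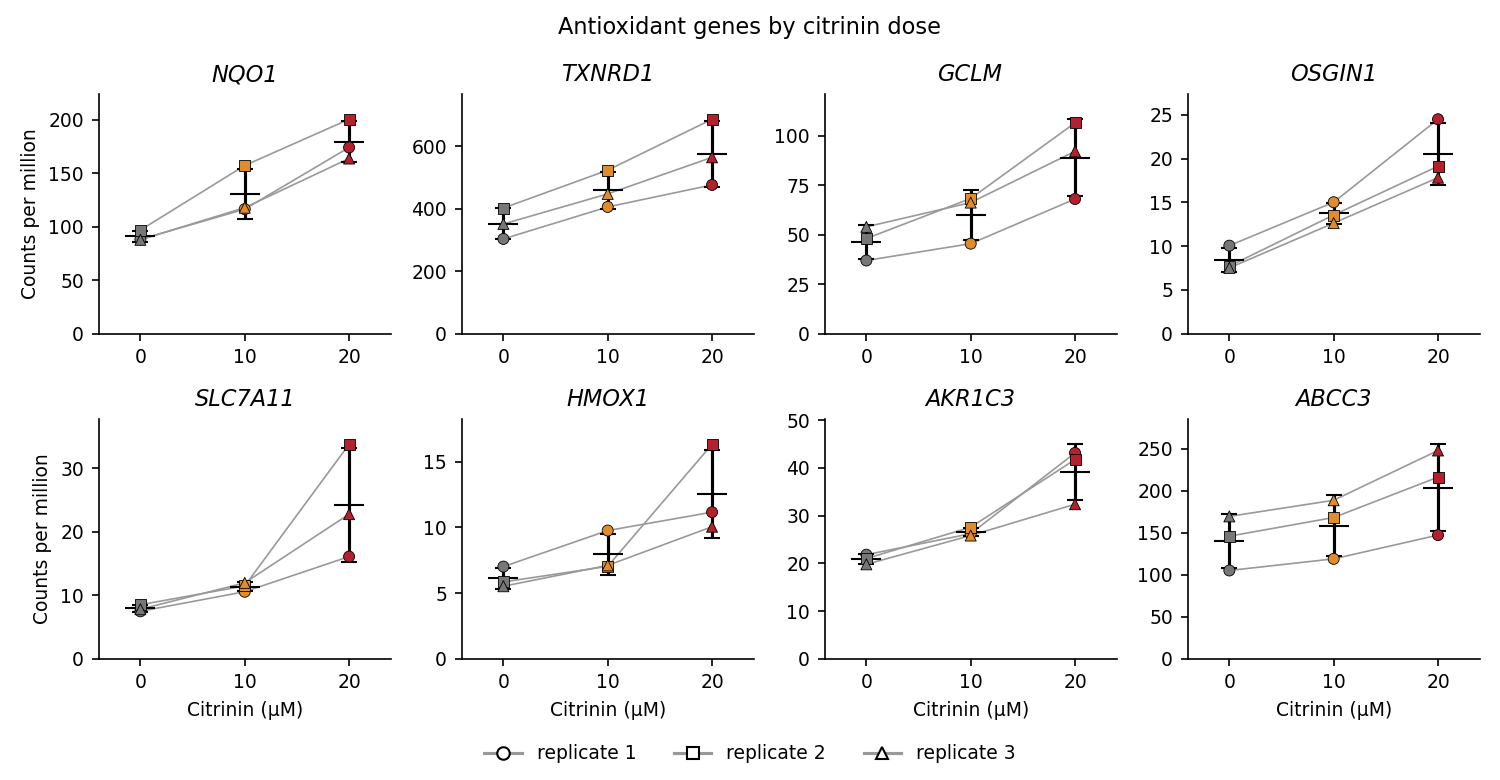
CPM of 8 antioxidant genes against citrinin dose in µM; symbols are single libraries, grey lines join libraries with the same replicate number, and black bars are the mean and SD of 3 libraries. All 3 lines of NQO1 climb, with means of 91.0, 131 and 179.6 CPM.

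Genes of sympathetic neuroblastoma identity were lower at 20 µM. RET, a receptor tyrosine kinase of sympathetic neuroblasts, fell from 325 ± 181 to 211 ± 98.6 CPM (-0.58 ± 0.06), and the neuroblastoma kinase ALK from 49.5 ± 8.25 to 36.3 ± 6.84 CPM (-0.45 ± 0.07). STMN2, a microtubule regulator of growing axons, fell from 691 ± 134 to 554 ± 85.9 CPM (-0.31 ± 0.05), and the transcription factor TFAP2B by 0.45 ± 0.07 on the log2 scale. The neurotrophin receptor NTRK2, named after its value was seen, fell by 0.79 on that scale. The edgeR adjusted p with the replicate block was 1.25e-05 for RET, 0.000147 for ALK, 0.000141 for STMN2 and 0.00025 for TFAP2B. RET (ENSG00000165731) spans 43077027 to 43130351 on chromosome 10, ALK (ENSG00000171094) 29192774 to 29921566 on chromosome 2, and STMN2 (ENSG00000104435) 79610814 to 79666175 on chromosome 8. Of the 24 genes of the list, 12 fell and none rose (16 fell adjusted over the list alone), with a median of -0.19. Camera gave an adjusted p of 3.82e-21 with the replicate block and 5.09e-06 without it. With an estimated correlation these were 0.108 and 0.413. Fry called the list with the block (adjusted p = 0.0296) and not without it (0.57).

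Some genes of other neuronal lists fell as well, and most members did not pass. Of 37 genes of axon guidance and neurite outgrowth, 6 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.09). The semaphorin receptors PLXNA4 (-0.36 ± 0.05) and PLXNA2 (-0.34 ± 0.05), the netrin receptor UNC5A (-0.57 ± 0.09) and the migration gene DCX (-0.35 ± 0.06) were among those that fell. Of 16 genes of catecholamine synthesis and handling, 4 fell (6 fell and 2 rose adjusted over the list alone; median -0.13). They were the granins CHGA (-0.40 ± 0.06) and CHGB (-0.31 ± 0.06), the noradrenaline-making enzyme DBH (-0.22 ± 0.05) and the decarboxylase DDC (-0.26 ± 0.07). Of 26 voltage-gated ion channel genes, 4 fell (6 fell and 1 rose adjusted over the list alone; median -0.09), among them CACNA2D2 (-0.49 ± 0.06), KCNC1 (-0.44 ± 0.10) and SCN9A (-0.21 ± 0.05). Of 29 postsynaptic and receptor genes, 3 fell, among them CHRNA7 (-0.34 ± 0.09) and NRXN2 (-0.31 ± 0.08), and 3 fell adjusted over the list alone (median -0.13). Of 28 synaptic vesicle genes, SV2C (-0.35 ± 0.06) and RAB3C (-0.28 ± 0.07) fell (5 fell and 1 rose adjusted over the list alone; median -0.12). Camera called each of these 5 lists lower with the replicate block, with adjusted p from 2.49e-08 to 0.00115. With an estimated correlation the adjusted p was 0.105 for axon guidance, synaptic vesicle and ion channel genes. It was 0.163 for postsynaptic genes and 0.346 for catecholamine genes. Fry with the block called the axon guidance (adjusted p = 0.0121), synaptic vesicle (0.0119) and ion channel (0.0158) lists. It did not call the postsynaptic (0.0661) and catecholamine (0.166) lists, and without the block fry called none of these 5 (0.954 for each). Without the block, the calls of the catecholamine (adjusted p = 0.364), synaptic vesicle (0.16) and ion channel (0.0639) lists were lost in camera, and the postsynaptic median became 0.06 without 20 µM replicate 1.

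Beside these falls, 6 of 36 mesenchymal genes, markers of the substrate-adherent cells that neuroblastoma cultures can hold, rose and none fell. They were CD44 (0.44 ± 0.05), TGFBI (0.41 ± 0.09), YAP1 (0.32 ± 0.07), ACTA2 (0.30 ± 0.06), VIM (0.21 ± 0.05) and ANXA2 (0.20 ± 0.05), named after their values were seen. The mesenchymal list as a whole had a median of -0.01 and was not called (camera with the block, adjusted p = 0.12). Adjusted over the list alone 7 rose and 3 fell. Those 3 were DCN (-0.47 ± 0.14), TWIST1 (-0.24 ± 0.06) and PRRX1 (-0.17 ± 0.06), also named after their values were seen. Glial and Schwann cell markers (median -0.11, adjusted p = 0.387) and epithelial markers (0.02, adjusted p = 0.363) were not called by camera either, and none of their members passed.

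**Figure D3:**
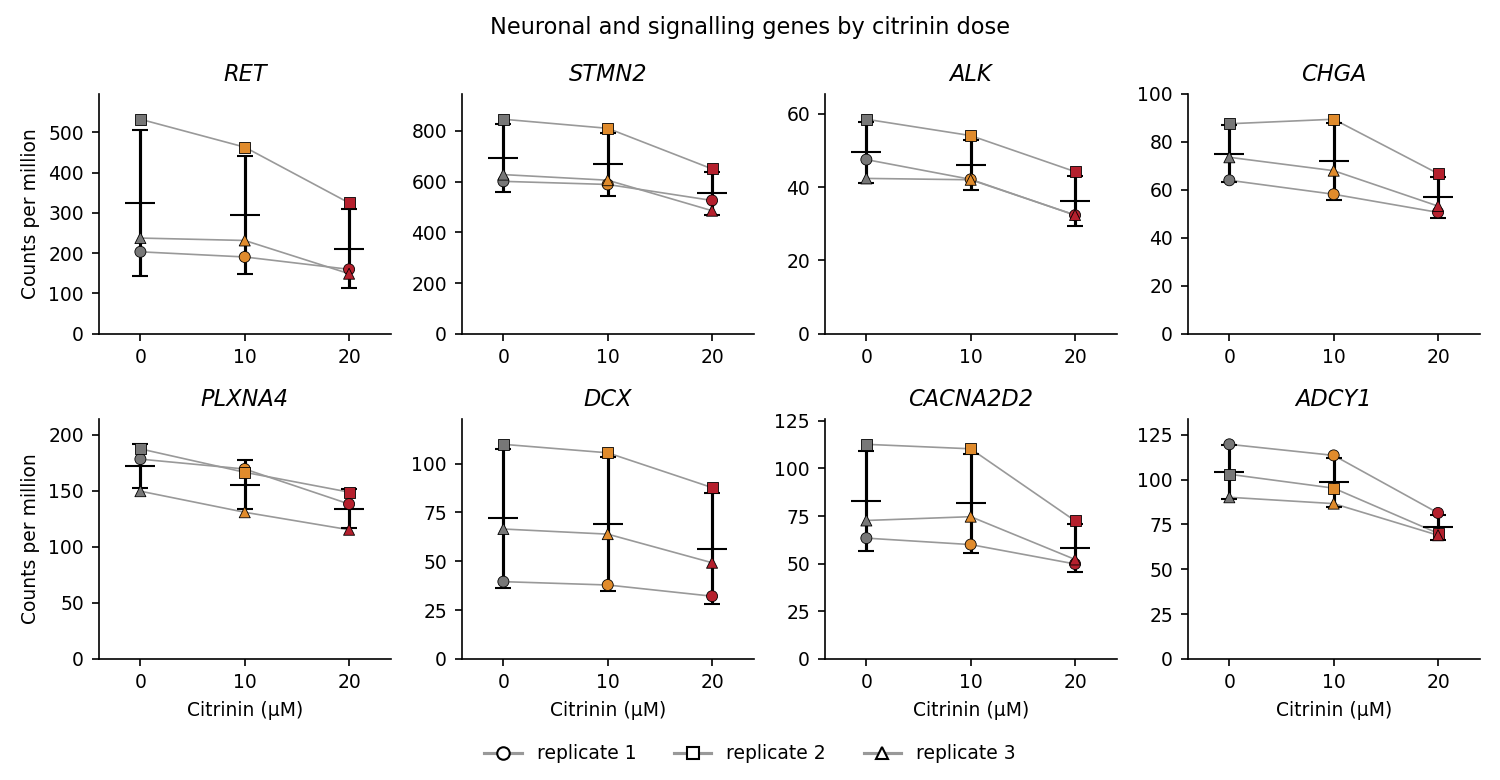
CPM of 8 neuronal and signalling genes against citrinin dose in µM; symbols are single libraries, grey lines join libraries with the same replicate number, and black bars are the mean and SD of 3 libraries. RET differs more between replicates (SD 181 CPM in vehicle) than between doses, and each of its 3 lines is lower at 20 µM than at 0 µM.

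A few genes of the stress and inflammatory lists rose at 20 µM, and most members did not pass. Of 20 inflammatory genes, CXCL8, the interleukin 8 gene (0.36 ± 0.05), NFKBIZ (0.36 ± 0.06) and IL1B (0.33 ± 0.06) rose, with 4 rising adjusted over the list alone (median 0.12). Of 21 cytosolic heat shock genes, DNAJB4 (0.35 ± 0.06), HSPA8 (0.18 ± 0.05) and HSPH1 (0.16 ± 0.04) rose, with 9 rising and 1 falling adjusted over the list alone (median 0.11). Of 29 p53 target genes, MDM2 (0.21 ± 0.05) and CDKN1A (0.18 ± 0.05) rose, with 5 rising adjusted over the list alone (median 0.16); BAX had a log2 fold change of 0.16 ± 0.05 and did not pass. Of 18 ferroptosis and iron genes, the transferrin receptor TFRC (0.35 ± 0.05), HMOX1 and the ferritin gene FTL (0.39 ± 0.06) rose, and 3 rose adjusted over the list alone (median 0.05); HMOX1 and FTL also belong to the NRF2 list, and FTL has processed pseudogenes that share its reads. Of 28 autophagy and lysosome genes, the cargo receptor SQSTM1 (0.30 ± 0.05), shared with the NRF2 list, rose, and 7 rose adjusted over the list alone (median 0.08). Camera with the replicate block called these 5 lists higher, with adjusted p from 1.18e-06 to 0.000195, and with an estimated correlation the adjusted p was 0.105 for autophagy and iron genes, 0.12 for inflammatory genes, 0.128 for heat shock genes and 0.265 for p53 targets. Fry with the block called the autophagy (adjusted p = 0.0119) and iron (0.00707) lists alone of these 5. Without the block fry called none of them (adjusted p of at least 0.568). The inflammatory list was not called by camera without the block (adjusted p = 0.364). In that fit the p53 median of 0.16 became -0.09 without vehicle replicate 1 and 0.01 without 20 µM replicate 2.

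Further lists were called with few or no single genes past the threshold. The 12 replication-dependent histones tested of 39 listed had a median of 0.28, above the sympathetic list's in size, and none passed; their mRNAs mostly lack poly(A) tails, and most were near 1 CPM. Camera's adjusted p with the block was 0.0101 for them (0.153 with an estimated correlation), and the call was lost without vehicle replicate 2 (median 0.14), 20 µM replicate 2 (0.15) or all replicate 2 libraries (0.07). Camera with the block called higher the 19 antioxidant enzymes outside the NRF2 list (median 0.11; SOD2 and PRDX6 rose, by 0.21 ± 0.05 and 0.17 ± 0.05), the 30 genes of glycolysis and hypoxia (0.09; PKM and EGLN3 rose), 24 genes of the unfolded protein response (0.06; EDEM1 rose), 30 proteasome subunits (0.08) and 45 nuclear-encoded respiratory chain subunits (0.05). The last 2 held no gene that passed. It called lower the 39 genes of mitosis (median -0.06; TOP2A and MKI67 fell, by 0.23 ± 0.05 and 0.20 ± 0.05), 39 genes of DNA replication (-0.08), 24 of DNA repair (-0.08) and 15 tubulins (-0.06), of which the last 3 held no gene that passed. Camera's adjusted p for these 10 lists, histones included, ran from 0.000119 to 0.0402, and from 0.153 to 0.672 with an estimated correlation. Adjusted over the list alone, 3 antioxidant enzymes, 5 glycolysis genes and 2 genes of the unfolded protein response rose, 5 mitosis genes and 1 tubulin fell, 1 DNA repair gene rose and 1 fell, and none passed among the other 4 lists. Without the block the median became -0.02 for the unfolded protein response without vehicle replicate 1, 0.03 for mitosis without vehicle replicate 2 and -0.02 for the respiratory chain without 20 µM replicate 1. With the block the DNA replication list turned to a median of 0.01 without 20 µM replicate 2 and 0.02 without all 3 libraries of replicate 2.

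The remaining lists were not called at 20 µM by camera with the block. The median was -0.03 for 34 targets of the integrated stress response (adjusted p = 0.448), 0.05 for 6 metallothionein and metal transport genes (0.937; 1 rose and 1 fell), 0.10 for 11 genes of the aryl hydrocarbon receptor (0.183; 1 rose) and 0.06 for 26 apoptosis regulators (0.437; 1 rose and 3 fell). It was -0.05 for 13 mitochondrially encoded genes (adjusted p = 0.238), -0.03 for 23 cholesterol genes (0.387) and -0.03 for 16 fatty acid synthesis genes (0.707; 1 rose and 1 fell). It was 0.00 for 38 ribosomal protein genes (adjusted p = 0.706), 0.00 for 27 MYC targets (0.937), -0.06 for 23 immediate early genes (0.707; 2 rose) and 0.07 for 28 interferon-stimulated genes (0.0741; 1 fell). The endoplasmic reticulum chaperone HSPA5 was at 517 ± 104 CPM in vehicle and 524 ± 79.4 CPM at 20 µM, a log2 fold change of 0.02 ± 0.05. The stress genes ATF3 (0.02 ± 0.15) and DDIT3 (-0.27 ± 0.23) did not pass, nor did CYP1A1 (-0.64 ± 0.32, 1.79 CPM on average in vehicle and 1.15 at 20 µM), HSPA1A (0.31 ± 0.09), GAP43 (-0.26 ± 0.09), TUBB (-0.14 ± 0.08) or CCNB1 (0.08 ± 0.06).

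The largest falls among genes averaging at least 2 CPM, with no overlap between the groups, were those of the potassium channel gene KCNH1 (-0.78 ± 0.15), the fucosyltransferase gene FUT9 (-0.61 ± 0.14), the DNA demethylase gene TET1 (-0.57 ± 0.09) and the proteases ADAMTS5 (-0.57 ± 0.09) and ADAMTS2 (-0.56 ± 0.12). CALCB (-0.56 ± 0.15), CLVS2 (-0.51 ± 0.07) and the adenylate cyclase ADCY1 (-0.50 ± 0.05) followed. In all, 393 of 17806 genes passed with the block in edgeR, 151 higher and 242 lower, with a median absolute log2 fold change of 0.31. Of these, 391 moved the same way in all 3 same-numbered pairs. The fit that picked them is blocked on these pairs, so this agreement is no independent support. No overlap between the groups was seen for 102 of them and for 6.76% of all tested genes. Chance gives 10% for exchangeable libraries, which these are not, since same-numbered libraries resemble each other, so the shares cannot be read as below or above chance. Changes of at least 2-fold numbered 9. SLC7A11, OSGIN1, SLCO2B1, HMOX1 and AKR1B10 (1.70 ± 0.38, 0.64 CPM on average in vehicle and 2.12 at 20 µM) rose. So did FBXW10B (1.60 ± 0.40), the ferritin pseudogene FTH1P2 (1.22 ± 0.33) and the long noncoding RNA LUCAT1 (1.13 ± 0.14). IL24 fell (-2.04 ± 0.53, 1.01 CPM on average in vehicle and 0.23 at 20 µM). Reads of FTH1P2 are hard to tell from those of the ferritin gene FTH1, which did not pass (0.37 ± 0.18). Those beyond SLC7A11, OSGIN1, SLCO2B1 and HMOX1 were named after their values were seen. Genes that fell had longer annotated transcripts than genes that rose (median 5770 against 3528 nucleotides, and 3236 over all tested genes).

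Without the replicate block edgeR called 0 genes at 20 µM, with 387 at an unadjusted p below 0.05 where chance gives 890.3 and a smallest adjusted p of 0.116, for AKR1C3, NQO1 and OSGIN1; DESeq2 called 11 and limma-voom 0. With the block DESeq2 called 266 and limma-voom 381. The blocked count of 393 moved to 204, 96 and 169 without vehicle replicate 1, 2 or 3, to 729 and 241 without 10 µM replicate 2 or 3, to 619, 249 and 149 without 20 µM replicate 1, 2 or 3, and to 48 without all replicate 3 libraries.

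The second comparison set 10 µM citrinin against vehicle. At this dose 6 genes rose and none fell with the replicate block, and 5 of the 6 belong to the NRF2 list. NQO1 rose 1.42-fold, from 91.0 ± 5.13 to 131 ± 23.2 CPM (SD, n = 3 per group; log2 fold change 0.51 ± 0.06 SE, adjusted p = 2.47e-05 in edgeR with the block). TXNRD1 rose from 353 ± 49.5 to 459 ± 59.7 CPM (0.38 ± 0.05), OSGIN1 from 8.44 ± 1.41 to 13.7 ± 1.20 CPM (0.71 ± 0.11) and GCLM from 46.3 ± 8.62 to 60.0 ± 12.6 CPM (0.37 ± 0.07). Outside the list ASPH, the aspartate beta-hydroxylase, rose (0.27 ± 0.05, adjusted p = 0.0454 in edgeR with the block), named after its value was seen. All 6 were higher in 3 of 3 same-numbered pairs, which the blocked fit that picked them favours, and 4 had no overlap between the groups. HMOX1 did not pass at 10 µM (0.39 ± 0.17).

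Of the 27 NRF2 antioxidant genes, 5 rose, none fell and 22 did not pass, while 18 rose adjusted over the list alone; the median log2 fold change was 0.24. Camera's adjusted p was 1.45e-46 with the block and 5.36e-26 without it, and with an estimated correlation 0.0501 and 0.0202. Fry did not call the list at this dose (adjusted p = 0.0874 with the block and 0.145 without it). Camera with the block called 6 further lists, in which no gene passed over all tested genes or adjusted over the list alone. Ribosomal proteins (median 0.07), respiratory chain subunits (0.06), antioxidant enzymes outside the NRF2 list (0.06), glycolysis and hypoxia genes (0.05) and proteasome subunits (0.05) were shifted upward, and sympathetic identity genes (-0.04) downward, with adjusted p from 0.000372 to 0.0108. With an estimated correlation their adjusted p was 0.701 to 0.708, and without the block camera called the respiratory chain list alone of these 6 (adjusted p = 0.0193). Without 10 µM replicate 2 the median was -0.03 for ribosomal proteins, -0.04 for respiratory chain subunits and -0.01 for antioxidant enzymes outside the NRF2 list, and the ribosomal list was then called downward by camera (adjusted p = 0.00862). Without the block the respiratory chain median became -0.00284 when the same library was left out. Among the sympathetic genes, TLX2 had a log2 fold change of -0.15 ± 0.05 and did not pass. The mesenchymal (median 0.02), glial (-0.06) and epithelial (0.06) lists were not called at 10 µM.

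Without the block edgeR called 0 genes at 10 µM, with 115 at an unadjusted p below 0.05, and DESeq2 and limma-voom also called 0; the smallest p values belonged to OSGIN1, the pseudogene LRRC37A6P and NQO1, which did not pass. The blocked count of 6 became 2 without vehicle replicate 1, 2 or 3 or 10 µM replicate 3, 16 without 20 µM replicate 1, 3 without 20 µM replicate 3 and 0 without all replicate 3 libraries.

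The third comparison tested the difference between the doses directly, 20 µM against 10 µM. SLC7A11 rose from 11.3 ± 0.71 CPM at 10 µM to 24.2 ± 8.93 CPM at 20 µM, 2.08-fold (SD, n = 3 per group; log2 fold change 1.05 ± 0.14 SE, adjusted p = 0.000517 in edgeR with the replicate block). OSGIN1 (0.57 ± 0.10), AKR1C3 (0.55 ± 0.08), GCLM (0.57 ± 0.06), NQO1 (0.47 ± 0.05), ABCC3 (0.36 ± 0.05) and TXNRD1 (0.32 ± 0.05) rose as well. TLR4, the receptor for bacterial lipopolysaccharide, rose from 12.4 ± 2.67 to 18.3 ± 2.35 CPM (0.57 ± 0.10), and the DNA end-joining factor APLF by 0.59 ± 0.13. ADCY1 fell from 98.4 ± 13.7 to 73.5 ± 6.89 CPM (-0.42 ± 0.05), and NBPF1 (-0.35 ± 0.07), the lipid flippase ATP8A1 (-0.30 ± 0.07) and PEG10 (-0.25 ± 0.04) fell. NBPF1 belongs to a family of near-identical copies, so its value is uncertain.

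Of the 27 NRF2 antioxidant genes, 10 rose between the doses and none fell (21 rose adjusted over the list alone; median 0.26). Camera's adjusted p was 1.42e-46 with the block, 0.0518 with an estimated correlation, and 1.75e-33 and 0.0101 without the block. Of the 24 sympathetic identity genes 4 fell, namely RET (-0.47 ± 0.06), ALK (-0.35 ± 0.07), TFAP2B (-0.33 ± 0.07) and STMN2 (-0.27 ± 0.05), and 14 fell adjusted over the list alone (median -0.17; camera with the block, adjusted p = 4.95e-18, and 0.145 with an estimated correlation). Of 20 inflammatory genes CXCL8 (0.36 ± 0.05), IL1B (0.39 ± 0.06) and NFKBIZ (0.26 ± 0.06) rose, and 6 rose adjusted over the list alone (median 0.11; camera with the block, adjusted p = 5.19e-09, and 0.137 with an estimated correlation). DCX (-0.30 ± 0.06) and PLXNA4 (-0.21 ± 0.05) of the axon guidance list, CHGA (-0.33 ± 0.06) of the catecholamine list and CACNA2D2 (-0.47 ± 0.06) of the ion channel list fell. Adjusted over the list alone, 12 axon guidance genes fell and 1 rose, 7 catecholamine genes fell and 1 rose, and 2 ion channel genes fell. Those 3 lists were called lower with the block, with medians of -0.09, -0.06 and -0.04 and adjusted p of 0.137, 0.545 and 0.158 with an estimated correlation in camera. Of the 36 mesenchymal genes 1 rose, CD44 (0.31 ± 0.05), and the list was not called (median 0.01).

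Camera with the block called 20 lists in this comparison, 9 higher and 11 lower, and 10 without it; with an estimated correlation it called none with the block and the NRF2 list alone without it. The lists called with the block alone were the inflammatory (camera adjusted p without it 0.144), axon guidance (0.0992), catecholamine (0.357), ion channel (0.27), synaptic vesicle (0.119), postsynaptic (0.103), mitosis (0.111), ribosomal (0.176), proteasome (0.119) and antioxidant enzyme (0.174) lists. The other lists called higher were p53 targets (median 0.12), histones (0.22), heat shock proteins (0.07), autophagy (0.08), iron genes (0.08), proteasome subunits (0.03) and antioxidant enzymes outside the NRF2 list (0.07). Those called lower were postsynaptic (-0.10) and synaptic vesicle genes (-0.11), DNA replication (-0.07), mitosis (-0.05), tubulins (-0.10), mitochondrially encoded genes (-0.11) and ribosomal proteins (-0.06). With an estimated correlation the adjusted p of these 14 lists was 0.137 to 0.681 in camera, and no gene of theirs passed. Fry with the block called the NRF2 and iron lists (adjusted p = 0.0312 for both). It also called the axon guidance, synaptic vesicle and autophagy lists (0.0418 for each). Without the block fry called the NRF2 list alone (0.0471). Adjusted over the list alone, 4 heat shock genes, 2 iron genes and 1 gene each of the p53, histone and autophagy lists rose, and 2 postsynaptic, 1 synaptic vesicle and 1 mitosis gene fell. The median became 0.04 for ribosomal proteins, then called upward by camera (adjusted p = 0.00169), and 0.04 for mitochondrially encoded genes without 10 µM replicate 2. It became -0.01 for ribosomal proteins without 20 µM replicate 2, 0.00 for DNA replication without 20 µM replicate 2, -0.01 for antioxidant enzymes without replicate 1 of either dose and -0.01 for the proteasome without all replicate 1 libraries. Without the block the p53 median of 0.13 became -0.13 without 10 µM replicate 1, called downward, and -0.03 without 20 µM replicate 2.

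With the block 79 genes passed in edgeR between the doses, 32 higher and 47 lower. All 79 moved the same way in 3 of 3 same-numbered pairs, which the blocked fit that picked them favours. Of them 15 had no overlap between the groups, against 4.87% of all tested genes. Without the block edgeR called 0, with 210 at an unadjusted p below 0.05, and DESeq2 and limma-voom called 0; the smallest p values belonged to SLC7A11, AKR1C3 and the pseudogene PERPP2, which did not pass. The blocked count of 79 moved to 50 without vehicle replicate 3, to 185 and 10 without 10 µM replicate 2 or 3, to 301, 32 and 26 without 20 µM replicate 1, 2 or 3, and to 174, 181 and 0 without all libraries of replicate 1, 2 or 3.

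**Figure D4:**
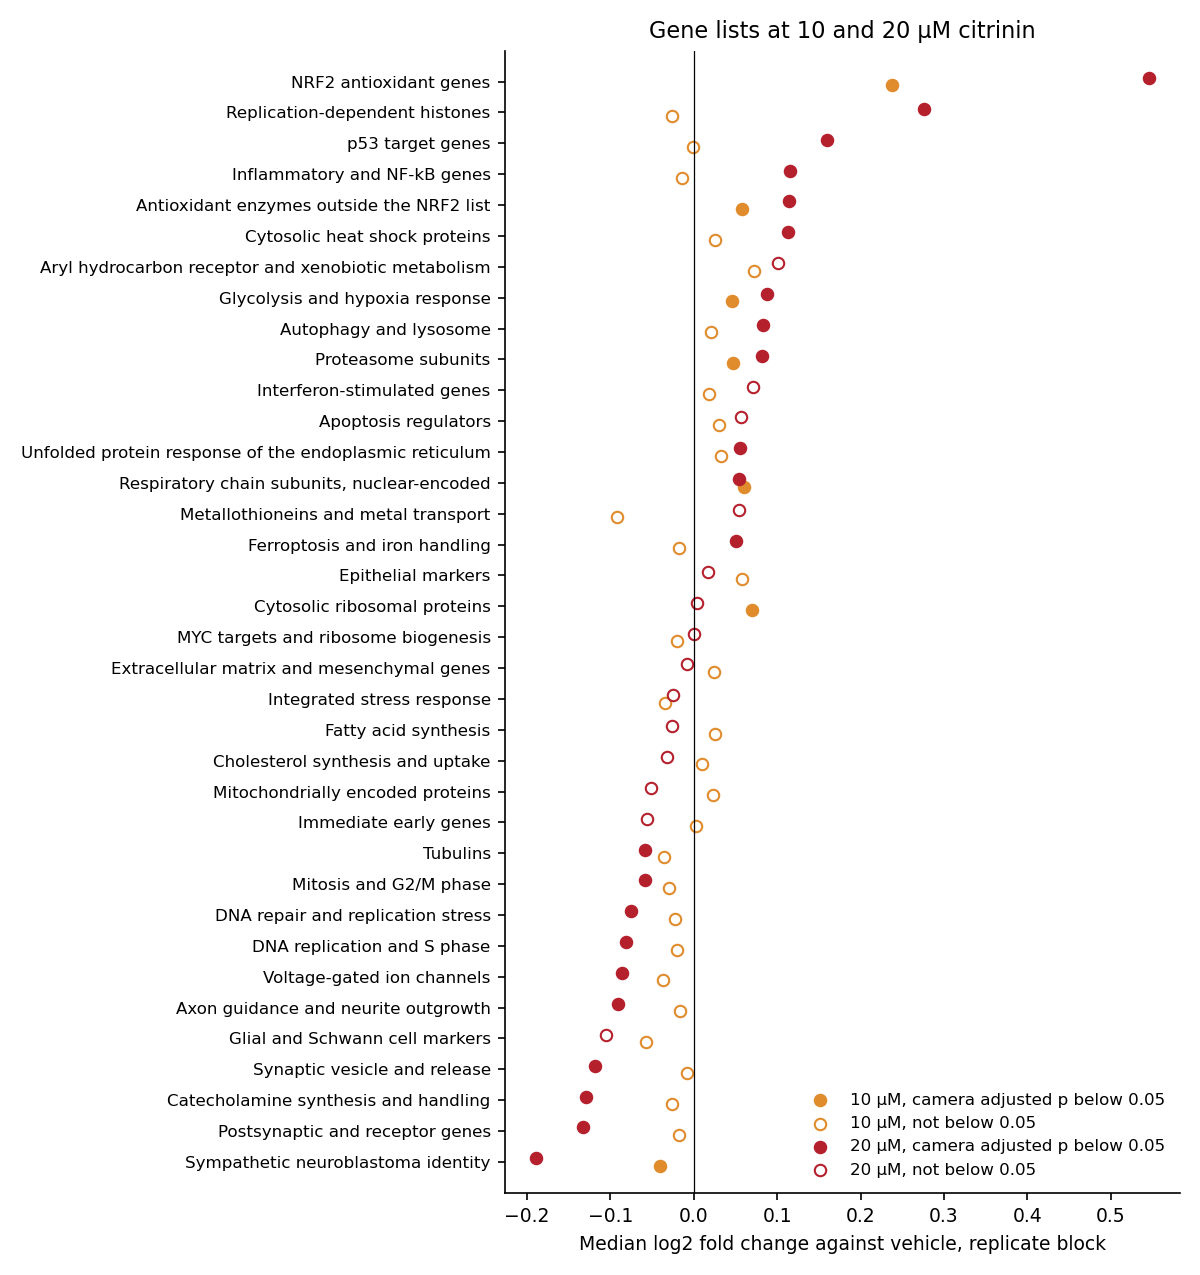
Median log2 fold change against vehicle of 36 gene lists at 10 µM (orange) and 20 µM (red) citrinin in the fit with the replicate block; filled symbols have a camera adjusted p below 0.05 at the preset correlation. The NRF2 list lies at 0.24 and 0.55, and the sympathetic list at -0.04 and -0.19.

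The doses were also compared by the genes they shared. All 6 genes called at 10 µM with the block (among them NQO1, TXNRD1, OSGIN1, GCLM and ASPH) were called at 20 µM in the same direction, where independent lists would share 0.0509 genes. In 20 simulations with the fitted changes kept at 20 µM and none at 10 µM, 0 to 3 genes were called at 10 µM; simulations of unchanged groups shared 0, but had hardly any calls to share. Of the 393 genes called at 20 µM, 375 (95.4%) had the same sign at 10 µM. Simulations chosen after the data were seen, with no change at either dose, gave 91.3% to 94.9%. That range is for the 393 genes with the smallest p at 20 µM, whether or not they passed, unlike the 393 genes called. With the fitted changes kept at 20 µM and none at 10 µM the simulations gave 53.2% to 66.6%. The observed share lay above both ranges. The vehicle libraries shared by the doses raise it, so how much of it comes from 10 µM is not known. The median ratio of the log2 fold changes at 10 and 20 µM was 0.31, between the means of 0.49 and 0.04 of these simulations, and 0.41 for the 20 NRF2 genes that rose, against -0.06 to 0.04 for the NRF2 genes called in the simulations without a change at 10 µM that kept the fitted changes at 20 µM. Between 20 and 10 µM, 78 of the 393 also passed. Across all tested genes the log2 fold changes of the doses had r = 0.51, where the simulations with shared vehicle libraries gave 0.50; the covariance was 0.0307 against 0.0248 simulated, a difference of 0.0059. Genes are not independent replicates, and part of the overlap can come from the shared vehicle libraries, which are too few to split.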

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

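Alternatives chosen only after the data were seen were the removal of length and GC trends, leaving out all libraries of 1 replicate number, the replicate number as a random effect, and all alternatives to the fit with the replicate block. The cause of the moves below was not tested unless named. In the planned fit the counts of called genes at 10 µM, at 20 µM, between the doses and at both doses were 0. With the replicate block they were 6, 393, 79 and 6, and the counts of called lists moved from 2 to 7 at 10 µM and from 10 to 20 between the doses. At 20 µM the planned fit called 6 genes with no filter, 11 with DESeq2, and 0 to 1 with single libraries left out (1 without 20 µM replicate 1). With the replicate number as a random effect it called 25, far fewer than the 393 with the number as a block. List counts of the planned fit with an estimated correlation were 1, 1 and 1 and with fry 0, 2 and 1 (10 µM, 20 µM, between doses). No filter gave 1 list at 10 µM and 4 between the doses, and leaving out mitochondrially encoded genes gave 5 between the doses. Leaving out libraries gave 2 to 19, 11 to 20 and 2 to 13 lists. At 10 µM it was 19, 4 and 9 without vehicle replicate 1, 2 or 3 and 10, 9 and 7 without 10 µM replicate 1, 2 or 3. At 20 µM it was 11 without vehicle replicate 2, and between the doses 6 without vehicle replicate 2 and 2 without 20 µM replicate 3.

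With the replicate block, the 6 genes at 10 µM became 23 with no filter, 12 with the 6 libraries of the comparison, 15 without length and GC trends, 2 with the counts of 1 strand, 0 at 2-fold and 3 at the threshold of 0.01, and 0 to 16 with libraries left out. The 393 at 20 µM became 644 with 6 libraries, 696 without length and GC trends (387 shared), 219 in the authors' table with no filter, 9 at 2-fold and 166 at 0.01, and 48 to 729 with libraries left out. The 79 between the doses became 188 with no filter, 30 with 6 libraries, 243 without length and GC trends, 1 at 2-fold and 40 at 0.01, and 0 to 301 with libraries left out. The 6 genes called at both doses became 19 with no filter, 11 with 6 libraries, 14 without length and GC trends and 2 with the counts of 1 strand, and 0 to 15 with libraries left out (2 without any 1 vehicle library or 10 µM replicate 3, 15 and 3 without 20 µM replicate 1 or 3, 0 without all replicate 3 libraries). In the planned edgeR fit, without the block, all 4 counts are 0; the alternatives to that fit that called genes at 20 µM are given above. Blocked list counts of 7, 22 and 20 became 0, 1 and 0 with an estimated correlation and 0, 7 and 5 with fry, and 2 and 10 without the block at 10 µM and between the doses. With libraries left out they were 1 to 11, 16 to 24 and 12 to 20: at 10 µM 11 without vehicle replicate 1 or all replicate 3 libraries and 1 without vehicle replicate 2, and between the doses 12 without 10 µM replicate 3.

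No named gene that was called reversed under any alternative. Of the called named genes, 35 of 56 at 20 µM, 2 of 5 at 10 µM and 12 of 25 between the doses stayed past the threshold in all 13 processing alternatives that keep the block, and 18, 0 and 0 in all 12 settings that leave libraries out. Of the called lists, 13 of 22, 1 of 7 and 8 of 20 stayed called in all 12.

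Direction changes were counted over all 36 lists in both fits, taking those where the list was called in either setting. Direction here is camera's, a list against all other genes, so the list's own median changed sign in 36 and kept it in 8. There were 44, all with libraries left out: 20 without the block (8 at 10 µM, 8 at 20 µM, 4 between the doses) and 24 with it (7, 3 and 14). The values given next are the 18 for lists called with the block; the restriction to these was made after the full count was seen. The other 26 came from lists not called with the block or from the fit without it: p53 targets, mitosis, respiratory chain, synaptic vesicle, catecholamine, inflammatory, mesenchymal, unfolded protein response, postsynaptic, ribosomal and mitochondrially encoded genes. Without the block, p53 targets between the doses went from 0.13 to -0.13 without 10 µM replicate 1 and were called both ways.

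With the replicate block, the ranges of medians over left-out libraries at 10 µM were -0.00885 to 0.129 for antioxidant enzymes outside the NRF2 list, -0.0379 to 0.139 for the respiratory chain (-0.0207 without replicate 2) and -0.0341 to 0.128 for ribosomal proteins (-0.0275 without replicate 2, called downward in both), each turned by 10 µM replicate 2. At 20 µM the range was -0.146 to 0.0225 for DNA replication (0.0102 without 20 µM replicate 2). Between the doses it was -0.0365 to 0.132 for antioxidant enzymes outside the NRF2 list (lowest without replicate 1; -0.00808 and -0.00986 without replicate 1 at 10 or 20 µM) and -0.125 to 0.00431 for DNA replication (highest without 20 µM replicate 2; -0.00731 without replicate 2). It was -0.176 to 0.0412 for mitochondrially encoded genes (0.0351 without 10 µM replicate 2), -0.137 to 0.0385 for ribosomal proteins (0.0385 without replicate 2, called upward; -0.00566 without 20 µM replicate 2) and -0.0133 to 0.0815 for the proteasome (lowest without replicate 1). At the preset correlation the block changed no call of a list from called to uncalled. With an estimated correlation it did so for the NRF2 list at 10 µM (adjusted p 0.0202 without the block, 0.0501 with it) and between the doses (0.0101 and 0.0518). Depth limits genes near 0.153 to 0.191 CPM, the level of 3 reads.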

Other observations

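The tests of library size, library batch, substrate-adherent cells and single replicates below were chosen only after the result was seen. The replicate numbers marked large differences between libraries that the doses do not explain. With dose in the model, edgeR called 7386 of 17806 genes between replicate 1 and the mean of replicates 2 and 3, 1105 of them at least 2-fold. The 3 libraries of a number differ in dose and may come from 1 culture. The p-values between replicate numbers therefore rest on the spread within a number and do not measure the spread between independent cultures. Targets of p53 were lower in replicate 1: 28 of 29 were lower, with a median log2 ratio of -0.81 (camera adjusted p = 2.0e-38, and 0.0364 with an estimated correlation). CDKN1A was at 168 ± 7.47 CPM in the replicate 1 libraries, 426 ± 44.7 in replicate 2 and 470.3 ± 26.5 in replicate 3 (SD over 3 doses). MDM2 was at 68.3 ± 2.13, 146 ± 18.9 and 166 ± 13.1 CPM, and GDF15 at 32.9 ± 1.23, 207 ± 21.4 and 153 ± 10.3 CPM.

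Other lists also differed between replicate 1 and the mean of replicates 2 and 3. Of 28 synaptic vesicle genes 21 were lower in replicate 1 and 4 higher (median -0.72), of 37 axon guidance genes 23 and 8 (-0.50), and of 20 inflammatory genes 10 and 4 (-0.34), each with a camera adjusted p of 0.0364 with an estimated correlation. Higher in replicate 1 were 22 of 36 mesenchymal genes, with 8 lower (median 0.32, camera adjusted p = 2.77e-14, and 0.0364 with an estimated correlation), 31 of 38 ribosomal protein genes, with none lower (0.37, 1.69e-13 and 0.408), and 14 of 24 sympathetic genes, with 7 lower (0.35, 7.83e-05 and 0.408). Among single genes, named after their values were seen, the neurofilament gene NEFL was at 27.1 ± 0.71 CPM in replicate 1 against 143 ± 7.19 and 119 ± 1.97 CPM in replicates 2 and 3, SNAP25 at 36.6 ± 0.87 against 128 ± 10.96 and 109 ± 7.37 CPM, and PTGS2 at 11.8 ± 0.995 against 277 ± 50.4 and 316 ± 13.3 CPM. Replicate 3 differed from replicate 2 in 2090 genes (edgeR), with 26 of 36 mesenchymal genes higher; COL1A1 was at 429 ± 25.1, 66.8 ± 3.37 and 287 ± 14.6 CPM in replicates 1, 2 and 3.

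The grouping of libraries by replicate number was set against technical explanations. The 2 libraries of 1 group that differ most in depth, 15678443 and 19604367 reads at 10 µM, had a chi-square per degree of freedom of 11.3. Pairs with replicate 1 had 25.4 to 36.4. This chi-square is scaled to the library totals, so it could hardly show an effect of library size and does not decide on it. Replicate 1 libraries had 16700919 to 17273034 reads, within the totals of the other libraries, so depth does not set them apart. Transcript length and GC content explained 5.40% of the variance of the replicate 1 ratios, and the p53 median stayed at -0.79 after their removal, which argues against a bias of that kind. The p53 median of -0.80 (means of log2 CPM) lay outside the range of -0.11 to 0.10 that holds the middle 95% of 10000 random lists matched on expression, but this list was picked because it differed, so the value excludes no batch. A library batch and a difference between the cultures behind each number, such as passage or day, may both remain; the labels record neither and no biological explanation was tested.

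The fall of sympathetic and neuronal genes at 20 µM is a candidate effect of the dose, found and tested on the same data. The tests by replicate number and by mesenchymal genes were chosen after it was seen. The values below for length, GC content and replicates are those of the sympathetic list, so they do not speak for the other neuronal lists. With length and GC trends removed the sympathetic list's median was -0.19, as before, and 13 of 24 genes fell, which argues against those trends. With all libraries of replicate 1, 2 or 3 left out the list stayed called lower at the preset correlation (median -0.26, -0.16 and -0.17, camera adjusted p at most 5.38e-12). The single pairs of libraries had medians of -0.11, -0.28 and -0.24. These medians argue against a single replicate carrying the change. With an estimated correlation the list was not called even on all libraries (camera with the block, adjusted p = 0.108). Fry, which does not compare the list with other genes, called it with the block (adjusted p = 0.0296) and not without it (0.57). A larger share of substrate-adherent cells cannot be told apart from lower expression in each cell: the mesenchymal median was -0.00840 (95% limits from resampling its genes -0.06 to 0.07), which met a bound set as evidence against it (not called upward, median below 0.1), and the bound was set aside after the value was seen because the members went both ways and how much of each transcript these cells supply is not known. Over all tested genes 6 of 36 rose, among them VIM at 427 CPM on average, and none fell; adjusted over the list alone 7 rose and 3 fell, 19 of 36 had negative values, and abundant matrix genes were near 0 (FN1 0.05 ± 0.05 at 3309 CPM, COL3A1 0.03 ± 0.05 at 1604 CPM, COL1A1 -0.05 ± 0.05).

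Splits of the 6 libraries of each comparison into 3 and 3 number 10, too few for a share below 0.05. With the replicate block, 1 of 10 splits gave as many genes as the 393 at 20 µM, the real one, and the highest other gave 0. Between the doses 1 of 10 gave as many as 79, and the highest other, which also parts all 3 pairs, gave 3. At 10 µM 2 of 10 gave as many as 6; the highest other gave 46, a split that parts 1 pair and keeps the other 2 pairs whole, and among the 4 splits that part all 3 pairs the highest other gave 0. In the planned fit without the block all 10 of 10 splits gave 0 genes in each comparison, the real one and the highest other alike.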
